A study of Arabidopsis thaliana with 12 samples.

How the data were processed

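The samples were Arabidopsis thaliana seedlings of the wild type Col-0 (WT) and of a pot1b mutant. POT1b is a paralogue of the telomere protein POT1a. Per the labels' protocols, seedlings were 6 days old and were kept for 6 h with 20 µM Zeocin, a bleomycin-type drug that breaks DNA strands, or with a mock treatment. The labels gave 4 groups of 3 libraries, named here WT mock, WT Zeocin, pot1b mock and pot1b Zeocin. They do not state which pot1b allele was used, nor whether the replicates came from separate cultures, so that p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was depleted of ribosomal RNA and libraries were made with a stranded kit.

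Each library came as a table of raw read counts per gene. Per the submitters' processing notes, the authors trimmed the reads with Trim Galore, aligned them with HISAT2 to TAIR10 and made the deposited counts with featureCounts, and limma was named as well; versions and the strand setting of the counting were not given. The values were whole numbers, and no table of the authors' own differential expression was used here. The tables held 34262 features, of which 6945 were at 0 in all libraries and 32548 had an entry in the TAIR10.1 gene table, an assembly name that differs from that of the counts. It was therefore used only for symbols, gene classes, neighbours and overlaps, and no coordinates are given. Of the other features, 1429 were small or ribosomal RNA models with their own names.

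Library totals ran from 9607269 to 24587168 counts, of which chloroplast genes took 53.01% to 58.45%, so that nuclear genes had 3961261 to 10490315 counts per library. A gene with 3 counts in a library, the floor used for genes at 0, corresponds to 0.122 to 0.312 CPM (counts scaled to a common library total). Where a group held 0 counts of a gene, the fold is a lower bound against 3 counts over that group's libraries. Where it held 1 to 3, the ratio is given with its exact 95% interval. Intervals and floors cover counting error only.

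Counting without strand cannot tell overlapping genes apart. Of 62 pairs of genes on opposite strands that overlapped over at least 90% of the longer one, 38 had equal counts (within 5% and 2 counts) in all 12 libraries, against 0 of 42 pairs of neighbours without overlap. Values of the 10082 nuclear genes that overlap another listed gene were therefore treated as uncertain. POT1B is one of them (with NHL3). Of the other genes named in these texts, so are TSO2, GMI1, SMR5, RAD50, POT1A, STN1, KN, ADH1, FER1, FRO3, XTH15, PYK10, WRKY33, WRKY40, HSP101, CAT2, GPX2, GR1, GSTU6, RBOHG, JAZ10, CHS, F3H, RCA, DIN6, ELF3, BOA, PPa2, AT4G12490, AT4G33666, AT5G10580 and AT5G25260.

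Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which removed 14666 features and left 19596. Libraries were scaled by TMM, and 1 model with the 4 groups was fitted to all 12 libraries with the robust quasi-likelihood F test, which left 8 residual degrees of freedom. The common dispersion was 0.0121, a coefficient of variation between replicates of 11%. There were 5 contrasts: Zeocin against mock in WT, Zeocin against mock in pot1b, pot1b against WT under mock, pot1b against WT under Zeocin, and the interaction, which is the Zeocin effect in pot1b minus that in WT. Adjusted p is edgeR's value with Benjamini-Hochberg adjustment over the 19596 genes of a contrast, unless a gene list is named. A gene was called at an adjusted p under 0.05. Levels are CPM scaled by TMM, given as mean ± SD with n = 3 libraries per group, and log2 fold changes are given with their standard error (SE). Single values per library were compared by exact two-sided permutation tests, where 3 libraries against 3 cannot give a p under 0.1.

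The contrasts, tests, alternatives, rule for named genes and 19 gene lists were fixed before the data were examined. The lists hold 295 genes, none in more than 1 list: telomere maintenance, DNA damage response and repair, G2/M cell cycle, S phase and DNA replication, ROS (reactive oxygen species) scavenging, ROS production, ROS-responsive transcripts, flavonoid synthesis, salicylic acid and immunity, jasmonate, abscisic acid and drought, heat shock, iron deficiency, photosynthesis, root markers, seed storage, shoot meristem, senescence and cell death, and the circadian clock. For each, called members were counted over all genes and with p-values adjusted over the list alone. Lists were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, with p-values adjusted over the 18 lists that had tested members. Camera was repeated with an estimated correlation. Fry was run as a separate test, which asks whether the genes of a list moved 1 way on balance and compares them with no other genes. Of the seed storage list, 0 of 8 members passed the filter, and the highest total of a member over all 12 libraries was 85 counts.

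Genes were named by rule. They were POT1B, POT1A and the 5 genes on each side of POT1B, and, per contrast, the 8 largest called changes in each direction with at least 1 CPM on average, nuclear and protein-coding, whose 3 libraries in 1 group all lay above the 3 of the other (without that last condition for the interaction). Up to 4 called members of each list with the smallest adjusted p were added. Genes so named in 1 contrast may be given in another. Product families (220 with enough tested members) were taken from the annotation after the results were seen.

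Alternatives were RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries and 100 counts in all), DESeq2 1.42.0, limma-voom, the 6 libraries of a contrast alone, the replicate number as a block, an adjusted p under 0.01, a fold change of at least 2, nuclear protein-coding genes alone, libraries thinned to the smallest total, and each library left out in turn. Offsets for GC content and gene length and a fit to genes without overlap were added after the results were seen. Chance was addressed by refitting other splits of the libraries. The edgeR steps were tested on simulated data for Zeocin in WT. Among 19411 genes, they recovered 56%, 80%, 90% and 100% of 50 genes each changed 1.5, 2, 4 and 8 times, and 11 of 174 calls (6.32%) were unchanged genes. The same run gave 7 interaction calls outside the changed genes. It gave each gene the same spread in all libraries and held no deviating library, so these rates need not hold for the real data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Splicing, transposons and gene ontology terms were not analysed here.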

Results

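Total RNA of 6-day-old Arabidopsis seedlings was sequenced in 12 libraries, 3 for each combination of genotype (WT Col-0 or pot1b) and treatment (mock or 20 µM Zeocin for 6 h). Total counts were 24587168, 9607269 and 21310003 in WT mock, 12721650, 18071814 and 18436247 in WT Zeocin, 20313243, 13766466 and 14465705 in pot1b mock, and 14800807, 11121224 and 13775919 in pot1b Zeocin (replicates 1, 2 and 3). Each library held counts for 22994 to 24358 features. The chloroplast gene psbA alone took 26.67% to 36.88% of a library. In a principal component analysis the first component (29.9% of the variance) set the Zeocin libraries apart from the mock libraries, and the second (22.1%) separated the genotypes within each treatment.

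POT1B (AT5G06310), the gene mutated in pot1b, was read at low depth in every library. WT mock libraries held 79, 28 and 68 counts and WT Zeocin libraries 47, 60 and 100. The pot1b mock libraries held 29, 14 and 39 counts and the pot1b Zeocin libraries 24, 8 and 56. The mean was 3.54 ± 0.897 CPM over the 6 WT libraries and 1.99 ± 1.3 CPM over the 6 pot1b libraries, so that 56.05% of the WT level was left. The difference averaged over treatments was -0.84 on the log2 scale and was not called (edgeR adjusted p = 0.13), and an exact two-sided permutation test within treatments gave p = 0.045. In both treatments replicate 3 of pot1b, at 2.82 and 4.21 CPM, lay near the WT level, while the other 4 pot1b libraries lay at 0.7 to 1.66 CPM. The level of POT1B thus did not check the labels of these 2 libraries, and the labels do not say which part of the gene the mutation interrupts. Over the genes that differed between genotypes, the pair sat with the other pot1b libraries, at median positions of 0.938 and 0.845 on a scale where WT is 0 and pot1b is 1. Neither the paralogue POT1A nor POT1B itself was called in any contrast with all libraries. Without pot1b Zeocin replicate 3, POT1B was called lower in pot1b under Zeocin (adjusted p = 0.013). That library had the highest POT1B level of its group, so that leaving it out favours the call. Under mock POT1B was not called whichever library was left out (lowest adjusted p = 0.101). Of the 10 neighbours of POT1B, NHL3, which overlaps it, was higher in pot1b under mock (log2 0.61, SE 0.12, adjusted p = 0.0015) and the cytokinin-activating gene LOG7 under Zeocin (0.55, SE 0.13, adjusted p = 0.006).

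The first comparison asked how WT seedlings respond to broken DNA. Zeocin raised the homologous recombination gene BRCA1 from 1.23 ± 0.13 to 85.9 ± 4.0 CPM (n = 3, log2 change 6.11, SE 0.10, adjusted p = 8.2e-22). TSO2, which codes for a ribonucleotide reductase subunit that supplies nucleotides for repair, rose from 4.60 ± 0.446 to 364 ± 23.2 CPM (6.31, SE 0.11). The cell-cycle inhibitor gene SMR7 rose by 7.36 (SE 0.29) to 39.5 ± 8.04 CPM, and the poly(ADP-ribose) polymerase gene PARP2 rose by 5.92 (SE 0.12) to 93.7 ± 12 CPM. XRI1, known from its rise after X-rays and needed for meiosis, gained 5.03 (SE 0.11). In all, 21 of the 31 tested DNA damage genes rose and 0 fell (21 and 0 adjusted over the list alone). Their median change was 2.96 (camera adjusted p = 1.6e-268, and 1.8e-06 with an estimated correlation). Other members that rose were COM1 (5.02), CYCB1;1 (4.20), the cohesin gene SYN2 (4.40) and AGO2 (2.73), a small-RNA effector. Among the 10 that were not called were the transcription factor gene SOG1, which carries the damage signal, at 0.04 and the break-sensing genes MRE11 (0.16), NBS1 (0.08) and RAD50 (0.12).

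Outside that list, the ATPase-type gene AT2G18193 rose from 1.85 ± 0.77 to 267 ± 15.7 CPM (7.28, SE 0.16). Some of the strongest rises came from transcripts with almost no counts under mock. AT5G07165 had 0 counts in WT mock and was at least 344-fold higher with Zeocin. The helicase-like AT1G20750 and the SAWADEE protein gene AT4G25330 were at least 70.6-fold and 57.5-fold higher. SMR5, a relative of SMR7, had 2 mock counts and a ratio of 140 (95% interval 38.5 to 1160), and KCS17, for fatty acid chain elongation, had 3 mock counts and a ratio of 123 (41.9 to 601).

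Zeocin also raised part of the oxidative stress transcripts in WT. Of 21 tested ROS-responsive genes 9 rose and 1, GSTU1, fell (11 and 3 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 9.9e-08, but adjusted p = 0.15 with an estimated correlation). The kinase gene OXI1, which acts in hydrogen peroxide signalling, rose from 0.633 ± 0.273 to 10.4 ± 0.986 CPM (4.19, SE 0.21, adjusted p = 6.6e-13). The mitochondrial genes OM66 and UPOX rose by 1.75 (SE 0.16) and 2.17 (SE 0.31), and WRKY33 by 0.95 (SE 0.14). Scavenging enzymes moved little: 0 of 25 rose and CSD2, DHAR1 and GPX2 fell, by at most -0.40 (2 rose and 5 fell adjusted over the list alone, median -0.07, adjusted p = 0.52). Of 16 genes for ROS production only the peroxidase gene PRX62 was called (-0.34), with 1 also adjusted over the list alone (median 0.04, adjusted p = 0.99).

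Genes of salicylic acid and immunity were higher as a list in Zeocin-treated WT (median 0.56, camera adjusted p = 2.3e-05, and 0.017 with an estimated correlation). Of 12 tested, 4 rose and 0 fell (7 and 0 adjusted over the list alone). SAG101, a partner of the immune regulator EDS1, rose from 16.9 ± 1.57 to 34.2 ± 5.73 CPM (1.02, SE 0.11), and CBP60G, a transcription factor gene for salicylate synthesis, rose by 0.91 (SE 0.10). Among single genes that fell, the alcohol dehydrogenase gene ADH1 dropped from 48.5 ± 3.22 to 15.8 ± 2.05 CPM (-1.62, SE 0.09, adjusted p = 6.7e-12). The peroxidase gene AT5G19890 fell from 36.1 ± 2.80 to 11.5 ± 1.76 CPM (-1.65, SE 0.12). The berberine-bridge-type gene AT1G30760 (-1.57), the glycine-rich gene AT2G05510 (-1.43), AT5G10580 (-1.35) and the dirigent gene DIR5 (-1.10) fell as well.

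The cell cycle lists stayed without called genes in WT, although fry called the G2/M and S-phase lists higher (fry adjusted p = 0.011 and 0.032). Of 20 G2/M genes 0 were called by edgeR, DESeq2 or limma-voom, with 5 at an unadjusted p under 0.05 (median 0.28, adjusted p = 0.51), and of 18 S-phase genes 0 were called by any of the 3 tools, with 2 at an unadjusted p under 0.05 (median 0.04, adjusted p = 0.85). Of 17 telomere genes 1 rose (1 adjusted over the list alone), STN1 of the complex that caps telomeres, by 0.57 (adjusted p = 0.041). That call was lost without 9 of the 12 libraries, each left out in turn, with an adjusted p of up to 0.16, and the list had a median of 0.08 (adjusted p = 0.52). Only AOC1 (0.57) was called of 12 jasmonate genes, where the median (-0.01) and the mean (0.02) differed in sign (1 adjusted over the list alone). PSAD1 (0.39) was the only one called of 17 photosynthesis genes (1 adjusted over the list alone), and their median of -0.04 and mean of 0.02 also differed in sign. Senescence genes had 2 of 6 lower, DIN6 and SEN1 (2 adjusted over the list alone, median -0.17, adjusted p = 0.41), and clock genes had LHY higher at 0.84 and BOA lower at -0.33 of 12 (1 and 1 adjusted over the list alone, adjusted p = 0.99). The abscisic acid, heat shock, flavonoid, iron, root and shoot meristem lists held 0 called genes by the same 3 tools. At an unadjusted p under 0.05 they had 2 of 11, 1 of 7, 3 of 7, 1 of 7, 2 of 7 and 0 of 3. Their camera adjusted p lay between 0.51 and 0.99, and for the iron list the mean (-0.03) and the median (0.04) had opposite signs. The root list's median was -0.02 while its test pointed up.

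Over all genes, 1174 changed with Zeocin in WT (655 up, 519 down), 310 of them at least 2-fold (280 up, 30 down). The count fell to 707 without WT mock replicate 1 and to 771 without WT mock replicate 3. The calls of CSD2, DIN6, GPX2, PRX62, PSAD1, SEN1 and BOA were each lost without at least 1 library, with adjusted p up to 0.13.

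**Figure D1:**
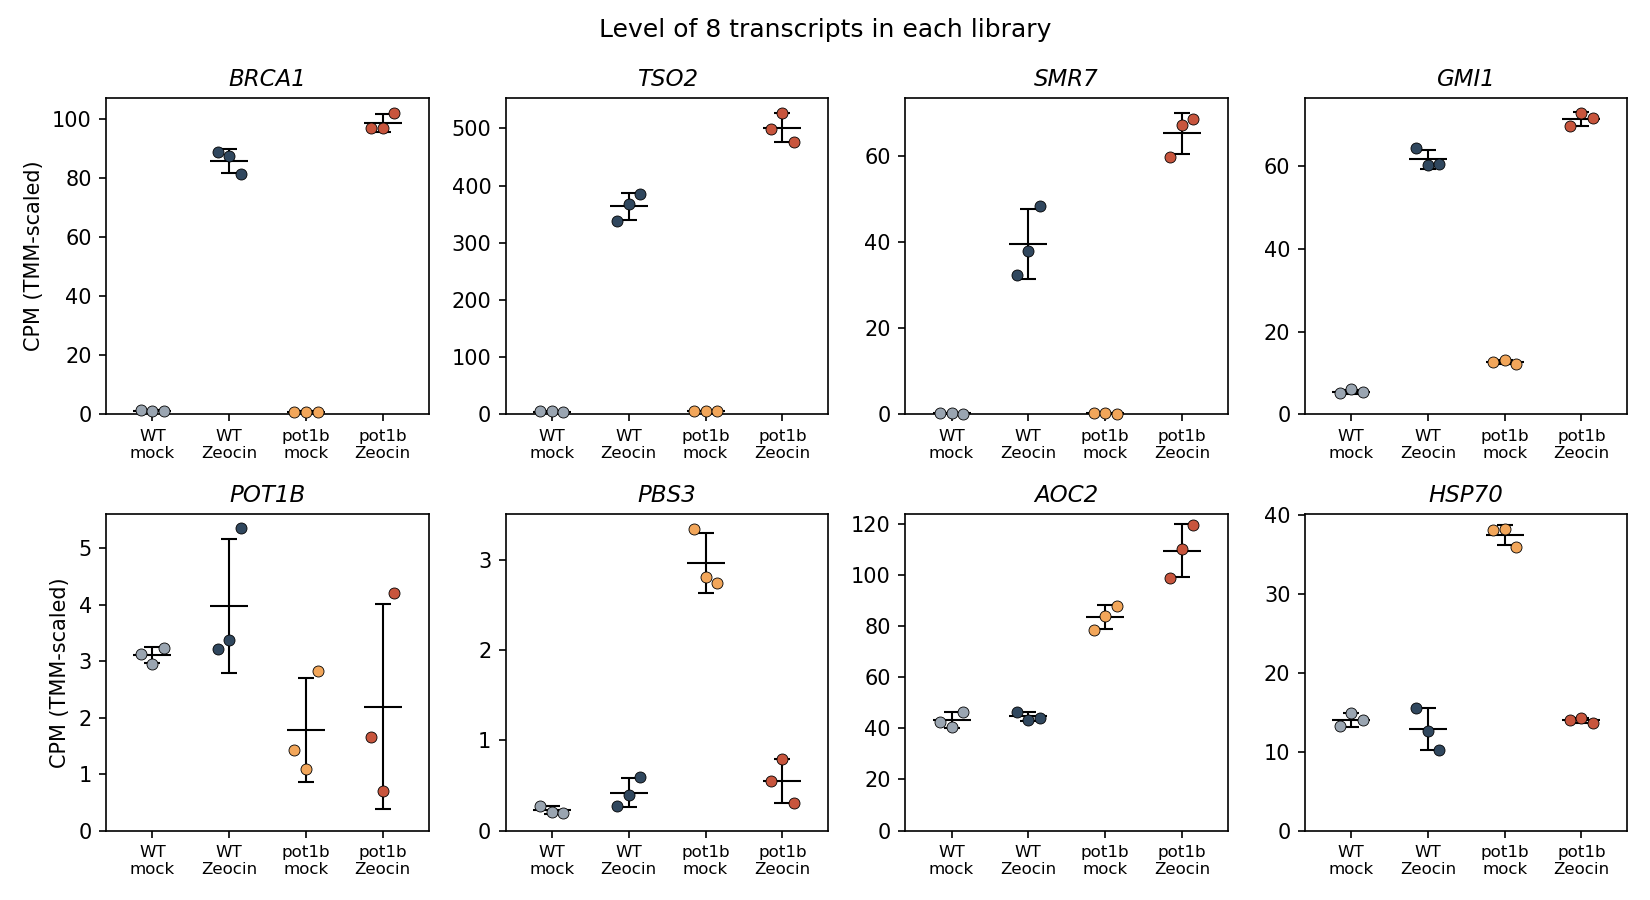
Levels of 8 genes in the 12 libraries, in CPM scaled by TMM on linear axes that start at 0; points are libraries, bars group means and whiskers the SD (n = 3). BRCA1, TSO2, SMR7 and GMI1 rose with Zeocin in both genotypes, POT1B was near the WT level in replicate 3 of pot1b, and PBS3 and HSP70 were high in pot1b mock.

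The second comparison asked for the same response in seedlings labelled pot1b. Zeocin raised BRCA1 in pot1b from 0.861 ± 0.0777 to 98.7 ± 2.98 CPM (6.81, SE 0.11, adjusted p = 4.0e-22), TSO2 to 501 ± 25.3 CPM (6.53, SE 0.11) and SMR7 to 65.1 ± 4.73 CPM (8.35, SE 0.30). The DNA damage list again had 21 of 31 members up and 0 down (21 and 0 adjusted over the list alone), with a median of 2.77 (camera adjusted p = 1.1e-262, and 1.1e-07 with an estimated correlation). AT5G07165 had 1 mock count in pot1b and a ratio of 1270 (227 to 50200), and AT4G22960 had 2 and a ratio of 345 (95 to 2850). OXI1 (3.64, SE 0.19), UPOX (2.19, SE 0.35), SAG101 (0.91, SE 0.11), WRKY40 (0.46) and the cytochrome P450 gene CYP81D8 (0.60) rose as well.

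In all 1313 genes changed in pot1b (725 up, 588 down), 338 of them at least 2-fold (275 up, 63 down). The count rose to 2033 without WT Zeocin replicate 1. The responses of the genotypes overlapped: 393 genes rose in both, where 24.2 would be shared by independent lists, 133 fell in both, against 15.6, and 6 were called in opposite directions. Across the 19596 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.688 and a Spearman correlation of 0.295. The comparisons share no libraries, but they share the spread estimate of each gene. Genes with a small spread can be called more easily in both, so the numbers for independent lists are a low baseline.

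Part of the changes in pot1b were reductions from a mock level above that of WT. The raised level and the reduction rest on the same 3 pot1b mock libraries. For such genes, this comparison, that of the genotypes under mock and the interaction are therefore not independent observations. PBS3, a gene for salicylate synthesis, dropped from 2.97 ± 0.331 to 0.547 ± 0.244 CPM (-2.46, SE 0.30, adjusted p = 4.1e-06). HSP70, a heat-inducible chaperone gene, dropped from 37.5 ± 1.27 to 14 ± 0.342 CPM (-1.42, SE 0.11, adjusted p = 2.2e-09). Of 7 heat shock genes 4 fell, among them HSP90.1 (-1.08) and HSP101 (-0.57), and HSFB2A rose by 0.47 (4 and 1 adjusted over the list alone). The list's median was -0.57 (camera adjusted p = 0.00038, but 0.22 with an estimated correlation). The calls of HSP101 and HSFB2A were lost without pot1b mock replicate 1 or pot1b Zeocin replicate 1 (adjusted p up to 0.092) and without pot1b mock replicate 3 (adjusted p = 0.053), respectively. The peroxidase genes PRX71 and PRX62 fell by -0.83 (SE 0.09) and -0.68 (SE 0.09), and PRX4 rose by 0.69 (SE 0.11). Of 16 ROS production genes 1 rose and 3 fell (3 and 5 adjusted over the list alone, median -0.10, adjusted p = 0.47). The main leaf catalase gene CAT2 (AT4G35090) fell by -0.46 (SE 0.08, adjusted p = 0.00029) and CSD2 by -0.42, the only 2 of 25 scavenging genes called (0 up and 5 down adjusted over the list alone, median -0.05, adjusted p = 0.47). Falls outside the lists included those of SOM (-1.80), which restrains seed germination, AT5G10580 (-1.75), AT2G44290 (-1.6), CSLB03 (-1.54), the nitrate transporter-type gene AT3G21670 (-1.53) and the calmodulin-like gene CML41 (-1.48).

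The ROS-responsive list had 8 of 21 members up and 0 down in pot1b (8 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 4.6e-06, but 0.22 with an estimated correlation). Of 12 jasmonate genes AOC1 (1.12, SE 0.10) and AOC2 (0.39) rose and JAR1 fell by -0.44 (3 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.12). The salicylic acid list had SAG101 up and PBS3 and ICS1 down (2 and 2 adjusted over the list alone), with a median of 0.08 and a mean of -0.07 (adjusted p = 0.99). RD29A (0.56) and KIN1 (0.50) rose of 11 abscisic acid genes (2 and 0 adjusted over the list alone), where the median (-0.09) and mean (0.08) differed in sign (adjusted p = 0.63). The iron transporter genes IRT1 (-0.92, SE 0.19) and OPT3 (-0.59, SE 0.11) fell of 7 iron genes (2 adjusted over the list alone, median 0.16, mean -0.09, adjusted p = 0.47). RBCS1A (-0.35), RCA (-0.33) and RBCS3B (-0.30) fell of 17 photosynthesis genes (1 up and 3 down adjusted over the list alone, median -0.10, adjusted p = 0.22). The calls of ICS1, KIN1, RBCS1A, RBCS3B and RCA were each lost without at least 3 of the libraries left out in turn, with adjusted p up to 0.19. No gene was called by edgeR, DESeq2 or limma-voom in the telomere, G2/M, S-phase, flavonoid, root, shoot meristem, senescence and clock lists. These had 2 of 17, 2 of 20, 3 of 18, 3 of 7, 2 of 7, 0 of 3, 2 of 6 and 4 of 12 genes at an unadjusted p under 0.05, and camera adjusted p-values of 0.22 or more. The telomere list's median was 0.03 while its test pointed down, and the clock list's median was -0.01 with a mean of 0.02.

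**Figure D2:**
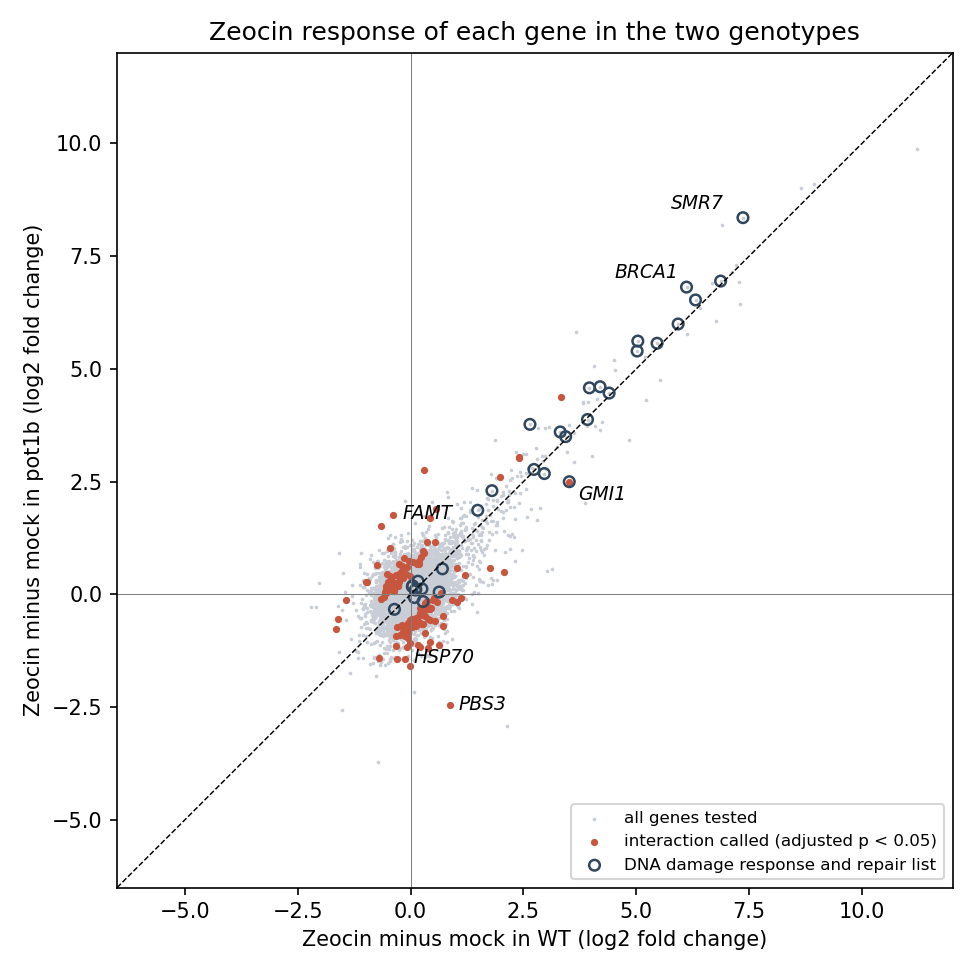
Log2 fold change by Zeocin in WT (x axis) and in pot1b (y axis) for the 19596 tested genes (grey), with the 147 genes called for the interaction in red and the 31 tested DNA damage genes ringed; the dashed line marks equal change. The DNA damage genes lay near that line, GMI1, PBS3 and HSP70 below it and FAMT above it.

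The third comparison asked how pot1b seedlings differ from WT without the drug. PBS3 was raised in pot1b from 0.226 ± 0.0456 to 2.97 ± 0.331 CPM (3.64, SE 0.33, adjusted p = 6.4e-08). RNS1, a ribonuclease gene induced by stress and phosphate shortage, rose from 6.08 ± 0.619 to 28.7 ± 3.40 CPM (2.23, SE 0.14, adjusted p = 4.5e-10). The iron uptake gene IRT1 rose from 1.33 ± 0.159 to 5.48 ± 0.137 CPM (1.99, SE 0.20), and its partner FRO2 by 1.3 (SE 0.19). Other genes that rose were AIG1 (2.79, SE 0.25), the hydrolase-type AT5G47330 (2.52, SE 0.18), AT5G46890 (2.49, SE 0.48), the lipid-transfer-type gene AT4G12490 (2.13, SE 0.14), the glutamate receptor gene ATGLR1.2 (2.09, SE 0.29) and the bHLH gene AT4G20970 (1.93, SE 0.11). Lower in pot1b were the cell wall gene XTH15, from 25.8 ± 2.43 to 9.17 ± 0.354 CPM (-1.49, SE 0.11, adjusted p = 1.9e-09), the auxin-responsive SAUR22 (-1.83, SE 0.31), FLP1 (-1.95, SE 0.32), the peroxidase gene AT3G03670 (-1.94, SE 0.29), the cytochrome P450 gene CYP96A5 (-1.48, SE 0.14) and RTFL21 (-1.54, SE 0.21), of a family of small growth-limiting peptides.

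Hormone and stress lists were raised in untreated pot1b. Of 12 salicylic acid and immunity genes 6 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 1.6e-08, and 0.0059 with an estimated correlation). They included CBP60G (1.31, SE 0.10) and ICS1 (1.21, SE 0.16), the gene of the main salicylate synthesis enzyme. Of 12 jasmonate genes 8 were higher and 0 lower (9 and 1 adjusted over the list alone, median 0.64, camera adjusted p = 1.5e-08, and 0.0058 with an estimated correlation). AOC2 rose from 43.3 ± 3.01 to 83.5 ± 4.70 CPM (0.94, SE 0.08) and AOS from 53.4 ± 2.92 to 93.8 ± 6.70 CPM (0.81, SE 0.08), both of jasmonate synthesis, and the repressor genes JAZ10 and JAZ1 rose by 0.90 and 0.58. Of 7 heat shock genes 5 were higher (5 up and 1 down adjusted over the list alone), among them HSP70 (1.42, SE 0.11, adjusted p = 5.1e-09), HSP101 (1.11) and HSP90.1 (0.87). Their median was 1.11 (camera adjusted p = 1.1e-06, but 0.053 with an estimated correlation). Iron genes had 3 of 7 higher and FRO3 lower at -0.34 (3 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.0059, but 0.053 with an estimated correlation). Of 11 abscisic acid genes COR15A (1.58, SE 0.17), KIN1 (0.66) and RD29A (0.36) were higher (3 and 0 adjusted over the list alone, median 0.18). That list's camera adjusted p was 0.033, against 0.32 with an estimated correlation, 0.094 without WT mock replicate 3 and 0.083 without pot1b mock replicate 1. Photosynthesis genes were higher in 6 of 17 (7 adjusted over the list alone), with LHCB1.1 at 0.54 and RBCS1A at 0.60 (median 0.30, camera adjusted p = 0.00025, but 0.22 with an estimated correlation).

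Of the genes of ROS metabolism, the process named in the study's title, scavenging genes went both ways while the called production genes were all higher. CAT3 (AT1G20620), a catalase gene, was lower in pot1b at 438 ± 18 against 702 ± 32.5 CPM (-0.68, SE 0.08, adjusted p = 2.2e-06). Of 25 scavenging genes 3 were lower and 3 higher (3 and 4 adjusted over the list alone), among them GR1 (-0.34) and GPX1 (0.25), with a median of -0.02 (adjusted p = 0.69). On the production side 4 of 16 were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.054). These were the NADPH oxidase genes RBOHD (0.57, SE 0.09, adjusted p = 7.7e-05) and RBOHC (0.73, SE 0.16) and the peroxidase genes PRX62 (0.58) and PRX71 (0.43). Of 21 ROS-responsive genes 7 were higher and 2 lower (8 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.006, but 0.32 with an estimated correlation). OM66 rose by 1.41 (SE 0.16), the zinc-finger gene ZAT12 from 5.75 ± 0.508 to 11.1 ± 0.399 CPM (0.95, SE 0.12) and the alternative oxidase gene AOX1A by 0.56 (SE 0.09). The ferritin gene FER1, which stores iron, was at 163 ± 5.52 against 305 ± 4.33 CPM (-0.90, SE 0.07, adjusted p = 9.4e-09).

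The DNA damage list as a whole was not raised in untreated pot1b (median 0.04, adjusted p = 0.48). Of its 31 genes 2 were higher (2 adjusted over the list alone): GMI1, a gene for repair by recombination, at 12.6 ± 0.452 against 5.48 ± 0.459 CPM (1.23, SE 0.09, adjusted p = 2.8e-09), and ERF115 (1.93, SE 0.51, adjusted p = 0.013), of stem cell renewal. BRCA1 (-0.50), TSO2 (0.25) and SMR7 (-0.27) were not called. Of 17 telomere genes TRP1 (AT5G59430), which codes for a protein that binds telomeric repeats, was higher by 0.44 (SE 0.10, adjusted p = 0.0027) and no other was called (1 adjusted over the list alone, median 0.07, adjusted p = 0.48). CDC20.1 (-0.67) and KN (-0.46) were lower of 20 G2/M genes (2 adjusted over the list alone, median -0.15, adjusted p = 0.071), and 0 of 18 S-phase genes were called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05 (adjusted p = 0.69). F3H (1.06) was the only call of 7 flavonoid genes (3 adjusted over the list alone, adjusted p = 0.26), and PYK10 (0.80, SE 0.07), for a beta-glucosidase of the root, that of 7 root genes (1 adjusted over the list alone), whose median (-0.02) and mean (0.17) differed in sign (adjusted p = 0.24). Of 3 shoot meristem genes 0 were called by the 3 tools, with 1 at an unadjusted p under 0.05 (adjusted p = 0.44). DIN6 (-0.64) and SEN1 (-0.61), both raised by darkness and sugar starvation, were lower of 6 senescence genes (2 adjusted over the list alone, adjusted p = 0.071). CCA1 (0.58) was higher and GI (-0.38) and PRR7 (-0.24) lower of 12 clock genes (2 and 4 adjusted over the list alone, median -0.12, adjusted p = 0.32).

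In all 2562 genes differed under mock (1420 higher and 1142 lower in pot1b), 341 of them at least 2-fold (266 higher, 75 lower). The count was 1595 without WT mock replicate 1 and 3981 when the 6 mock libraries were fitted alone. The calls of ERF115, CDC20.1, KN, F3H, FRO3, RD29A, GR1, GPX1, CCA1 and PRR7 were each lost without at least 1 library, with adjusted p up to 0.21.

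The fourth comparison asked how the genotypes differ once both have met Zeocin. Of 31 DNA damage genes 7 were higher in pot1b and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0031, but 0.11 with an estimated correlation). TSO2 stood at 501 ± 25.3 against 364 ± 23.2 CPM (0.46, SE 0.08, adjusted p = 0.00062), SMR7 at 65.1 ± 4.73 against 39.5 ± 8.04 CPM (0.72, SE 0.15, adjusted p = 0.0087), COM1 at 19.9 ± 0.372 against 13.7 ± 1.66 CPM (0.54, SE 0.12) and PARP2 at 120 ± 3.97 against 93.7 ± 12 CPM (0.36, SE 0.08).

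Jasmonate genes were the list that stood out most in Zeocin-treated pot1b, with 7 of 12 higher and 0 lower (9 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 2.0e-17, and 0.00049 with an estimated correlation). AOC2 was at 110 ± 10.3 against 44.7 ± 1.68 CPM (1.29, SE 0.08, adjusted p = 5.8e-10), AOC1 at 42.3 ± 5.90 against 20.5 ± 0.821 CPM (1.04, SE 0.10) and AOS at 99.2 ± 10.3 against 48.0 ± 3.33 CPM (1.05, SE 0.09). The methyltransferase gene FAMT had 15.7 ± 1.43 against 2.89 ± 0.843 CPM (2.41, SE 0.17, adjusted p = 3.2e-09). RNS1 (2.21, SE 0.14), AT4G20970 (1.88, SE 0.12), IRT1 (1.68, SE 0.24), FRO2 (1.38, SE 0.19), AT5G46890 (2.29, SE 0.34) and AT5G62360 (1.93, SE 0.16) were higher and XTH15 (-1.75, SE 0.11), XTH33 (-1.53, SE 0.26) and AT3G03670 (-1.37, SE 0.21) lower, on the same side as under mock. Abscisic acid genes had COR15A (1.75, SE 0.18), KIN1 (1.55, SE 0.15) and RD29A (0.98, SE 0.11) higher of 11 (5 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 1.3e-05, but 0.16 with an estimated correlation).

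CAT3 (AT1G20620) stayed lower in pot1b with Zeocin (-0.52, SE 0.08, adjusted p = 0.00012), and GPX1 (0.33) and DHAR1 (0.30) were higher, the only 3 of 25 scavenging genes called (4 up and 5 down adjusted over the list alone, median -0.04, adjusted p = 0.70). ROS production genes had PRX4, RBOHD and RBOHG higher and PRX37 lower of 16 (4 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.69). The glutathione transferase genes GSTU24 (0.95, SE 0.15) and GSTU1 (0.93, SE 0.16) and the transcription factor gene NAC032 (0.71, SE 0.12) were higher and FER1 lower (-0.84, SE 0.07). The ROS-responsive list had 7 of 21 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.022, but 0.53 with an estimated correlation). Without WT Zeocin replicate 2 or 3 or pot1b Zeocin replicate 1 or 2, that list's adjusted p was 0.14, 0.17, 0.084 and 0.055. EDS1 (0.37) and SAG101 (0.52) were higher of 12 salicylic acid genes (2 and 0 adjusted over the list alone, median 0.13, adjusted p = 0.33). PBS3 (0.32), CBP60G (0.26) and ICS1 (0.32) were no longer called.

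IRT1 and FRO2 were the 2 of 7 iron genes called (2 up and 2 down adjusted over the list alone, median 0.30, adjusted p = 0.12), and LHCB1.1 (0.51) the only one of 17 photosynthesis genes (1 adjusted over the list alone, median 0.08, adjusted p = 0.077). CHS (0.62) was called of 7 flavonoid genes (1 adjusted over the list alone), with a median of -0.03 and a mean of 0.01 (adjusted p = 0.91). PYK10 (0.83) was higher and SCR (-0.69), of root patterning, lower of 7 root genes (1 and 2 adjusted over the list alone, median -0.37, adjusted p = 0.91). DIN6 (-0.35) and SEN1 (-0.44) were lower of 6 senescence genes (2 adjusted over the list alone, adjusted p = 0.35), and ELF3 (-0.29) of 12 clock genes (1 adjusted over the list alone), where the mean was 0.03 and the test pointed down (adjusted p = 0.70). The telomere, G2/M, S-phase, heat shock and shoot meristem lists had 0 calls by edgeR, DESeq2 or limma-voom. They had 2 of 17, 3 of 20, 3 of 18, 2 of 7 and 1 of 3 genes at an unadjusted p under 0.05, and camera adjusted p-values of 0.70, 0.28, 0.91, 0.35 and 0.32. Adjusted over the list alone, 2 heat shock genes were higher.

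Over all genes 2168 differed under Zeocin (1284 higher and 884 lower in pot1b), 212 of them at least 2-fold (188 higher, 24 lower). Of these, 637 were higher and 400 lower under mock as well, where independent lists would share 93 and 51.5, and 12 changed sides. Here too the spread estimate of each gene was shared, so that baseline is low. The count was 1239 without pot1b Zeocin replicate 1 and 928 (69.5% of them higher) when the 6 Zeocin libraries were fitted alone. The calls of RBOHD, RBOHG, PRX37, DHAR1, CHS, SCR and ELF3 were each lost without at least 1 library, with adjusted p up to 0.11.

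**Figure D3:**
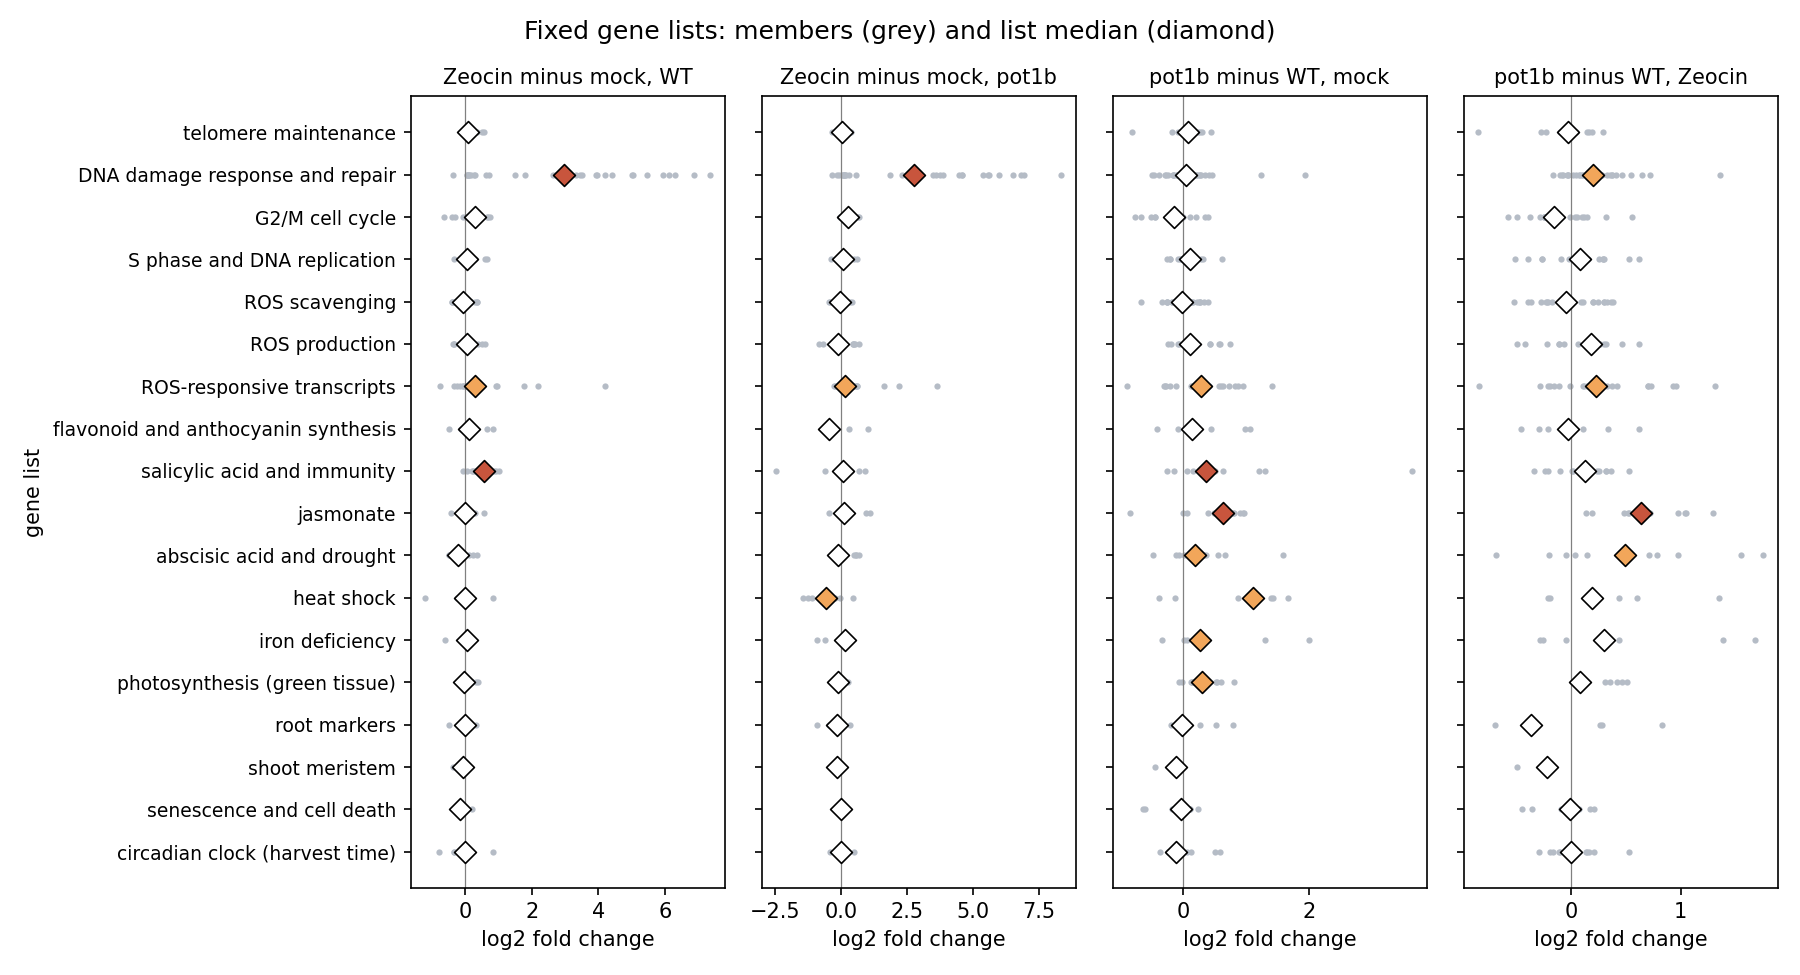
Log2 fold changes of the tested members of 18 gene lists in the 4 comparisons of groups; grey dots are genes and diamonds list medians, red where camera's adjusted p was under 0.05 with the preset and the estimated correlation, orange with the preset one alone and white with neither. DNA damage genes had medians of 2.96 and 2.77 with Zeocin, and jasmonate genes 0.64 in pot1b against WT under both treatments.

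The interaction asked whether pot1b responds to Zeocin differently from WT. It was called for 147 genes, 73 with a lower and 74 with a higher Zeocin effect in pot1b, 33 of them with a difference of at least 2-fold. The largest lower effect was in PBS3 (-3.33, SE 0.57, adjusted p = 0.0046), which had 0.226 and 0.419 CPM in WT without and with Zeocin (not called) and fell from 2.97 to 0.547 CPM in pot1b. Its WT mock level lay within the range of the 3-count floor (0.122 to 0.312 CPM), so this difference rests on few WT counts. DESeq2 gave no adjusted p for it. HSP70 (-1.29, SE 0.16, adjusted p = 0.00018), CBP60G (-1.05, SE 0.14), OM66 (-1.18, SE 0.21), PRX71 (-0.65, SE 0.12), AT4G12490 (-1.13, SE 0.21), AT3G60415 (-1.57, SE 0.28) and AT5G25260 (-1.36, SE 0.14) had lower effects as well. In HSP70 the level was 14.1 and 12.8 CPM in WT and 37.5 and 14 CPM in pot1b, without and with Zeocin. Of the DNA damage list only GMI1 was called, with a smaller rise in pot1b (-1.02, SE 0.11, adjusted p = 8.3e-05). It reached 61.7 CPM in WT and 71.4 CPM in pot1b, from different mock levels. The other 30 members included BRCA1 (0.70), SMR7 (0.99) and TSO2 (0.22) and were not called. Over all 31 members, GMI1 included, 1 was higher and 1 lower adjusted over the list alone (median 0.08, camera adjusted p = 0.54).

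The largest higher effect among named genes that were called whichever of the 12 libraries was left out was in FAMT (2.16, SE 0.25, adjusted p = 0.00012). Its level was 3.92 and 2.89 CPM in WT and 4.64 and 15.7 CPM in pot1b. CYP96A5 (1.27, SE 0.18) rose from 2.70 to 8.81 CPM in pot1b and from 7.59 to 10.2 CPM in WT, and AT1G14120 (1.48, SE 0.21) and the glycine-rich GRP9 (1.24, SE 0.20) also had higher effects. ADH1 (1.07, SE 0.13, adjusted p = 0.00018) and AT5G19890 (0.89, SE 0.18) fell less in pot1b than in WT.

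Of the 147 genes, 103 differed between genotypes under mock and 76 under Zeocin, counts that share libraries with the interaction. As lists, salicylic acid and immunity genes had a lower Zeocin effect in pot1b (median -0.20, camera adjusted p = 5.9e-06, and 0.014 with an estimated correlation), with PBS3 and CBP60G called of 12 (0 up and 4 down adjusted over the list alone, and 1 called by DESeq2). So did heat shock genes (median -0.68, camera adjusted p = 0.00018, but 0.22 with an estimated correlation), with HSP70 and HSP90.1 called of 7 (3 down adjusted over the list alone). In scavenging genes DHAR1 (0.48) and GPX2 (0.50) were called of 25 (2 and 2 adjusted over the list alone), with a median of -0.01 and a mean of 0.01 (adjusted p = 0.94). PRX71 was called of 16 ROS production genes (2 and 2 adjusted over the list alone, median -0.20, adjusted p = 0.17) and OPT3 of 7 iron genes (1 adjusted over the list alone), with a median of 0.06 and a mean of -0.06 (adjusted p = 0.50). OM66 was called of 21 ROS-responsive genes (2 and 1 adjusted over the list alone), with a median of 0.01 and a mean of -0.03 (adjusted p = 0.57). Of 12 jasmonate genes 0 were called over all genes but 4 up adjusted over the list alone, with 5 at an unadjusted p under 0.05 (median 0.10, adjusted p = 0.089). DESeq2 and limma-voom called 0 of them. Of 11 abscisic acid genes edgeR and limma-voom called 0 and DESeq2 2, with 2 at an unadjusted p under 0.05 and 2 up adjusted over the list alone (adjusted p = 0.074). Of 17 photosynthesis genes edgeR and limma-voom called 0 and DESeq2 1, with 4 at an unadjusted p under 0.05 (1 down adjusted over the list alone, adjusted p = 0.097). The 3 tools called 0 genes in the telomere, G2/M, S-phase, flavonoid, root, shoot meristem, senescence and clock lists, which had 1, 1, 0, 1, 0, 0, 1 and 1 genes at an unadjusted p under 0.05 and camera adjusted p-values of 0.17 or more. Adjusted over the list alone, 1 flavonoid gene had a lower and 1 clock gene a higher effect, and the S-phase list's mean was 0.00 with a median of -0.01.

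The count of 147 rose to 437 without WT Zeocin replicate 1, the library least like its group, and lay between 56 and 84 without any 1 of 8 other libraries. It was 91 with limma-voom. Of 25 genes named by rule for the interaction, 13 lost the call without at least 1 library, among them HSP90.1, OPT3, DHAR1 and GPX2, with adjusted p up to 0.21.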

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

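The tests of GC content and gene length, of depth and of harvest time, of a single deviating library, of whether pot1b mock seedlings alone stood apart, and of a standing response to damage or Zeocin were chosen only after the results were seen. Bootstrap intervals in this section resampled genes and not libraries. They treat genes as independent and leave out the spread between libraries.

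The Zeocin effect differed between genotypes by the interaction test in 28 named genes (log2, pot1b minus WT). It was lower in pot1b in PBS3 (-3.33), AIG1 (-1.76), AT2G44290 (-1.58), AT3G60415 (-1.575), AT4G33666 (-1.57), AT3G47480 (-1.49), PPa2 (-1.42), AT5G25260 (-1.36), HSP70 (-1.29), OM66 (-1.175), AT4G12490 (-1.13), HSP90.1 (-1.08), CBP60G (-1.05), GMI1 (-1.02), PRX71 (-0.65) and OPT3 (-0.63). It was higher in AT2G18210 (2.17), FAMT (2.16), AT1G14120 (1.48), IAA29 (1.32), AT2G05510 (1.3), CYP96A5 (1.27), LBD25 (1.25), GRP9 (1.24), ADH1 (1.07), AT5G19890 (0.89), GPX2 (0.50) and DHAR1 (0.48). Of the 25 named by rule for the interaction, 13 lost the call without at least 1 library. They were AIG1, AT2G05510, AT2G18210, AT2G44290, AT3G47480, AT4G33666, PPa2, HSP90.1, OPT3, IAA29, LBD25, GPX2 and DHAR1. IAA29 and OPT3 lost it in 11 of the 12 refits and AT2G18210 in 5. DESeq2 did not call, or gave no adjusted p for, 11 of the 25. As lists, salicylic acid and immunity genes (camera adjusted p = 5.9e-06) and heat shock genes (0.00018, but 0.22 with an estimated correlation) had a lower effect in pot1b.

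Of 100 splits of the genotypes within treatments, 1, the real one, gave as many interaction calls as 147. The next highest gave 139, and kept the mock groups as labelled while WT Zeocin replicate 1 and pot1b Zeocin replicate 3 changed places. Splits that changed the mock groups gave at most 2 calls, and in them the differences between genotypes under mock enter the spread. The 10 splits that kept the mock groups gave 27 to 147 calls and are too few for a share under 0.05. Of 100 pairs of splits by treatment, 1, the real one, gave as many genes called in the same direction in both genotypes (526), and the highest other gave 0. The other pairs mixed mock and Zeocin libraries in at least 1 genotype, which alone left 0 calls there, so this count does not test the overlap against chance. For the 4 comparisons of groups, the 10 possible splits are too few for a share under 0.05: the real counts were 1174, 1313, 2562 and 2168, each reached by 1 split, and the highest other counts 0, 0, 0 and 7.

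The first pattern is a set of 63 genes with an interaction call that were higher in pot1b under mock (median difference 1.03) and had a lower Zeocin effect there. When genes were chosen by the same rule without pot1b mock replicate 1, 2 or 3 (39, 32 and 32 genes), their median excess over WT mock in the library left out was 0.925, 1.02 and 1.11 (lowest bootstrap 95% bound 0.751), which argues against a single deviating library. A standing DNA damage response of the damage genes as a group is argued against by the 21 raised by Zeocin in WT (median 3.96). Their median difference between genotypes under mock was 0.0412 (bootstrap 95% interval -0.17 to 0.21). Of the 21, 1 was called higher in pot1b under mock, GMI1, which is also among the 63. A median cannot exclude a standing rise in part of the genes. Under Zeocin the median difference of the 63 was 0.1361 (quartiles -0.18 to 0.32) and 46 of them were lowered by Zeocin in pot1b, values that the choice of genes favours, so that mock seedlings of pot1b set apart by handling or growth cannot be told apart from an effect of the genotype that Zeocin cancels, because such handling would follow the groups and the labels record none. A standing rise in pot1b of other genes that respond to Zeocin stays open: 19 of the 63 (30.2%, against 3.34% of all tested genes) were raised by Zeocin in WT, part of which could come from the WT mock libraries that both comparisons share.

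The second pattern is the number of genes that differed between genotypes under mock, 2562. With offsets for GC content and gene length 2477 were called, and with all libraries thinned to the smallest total 1987, which argues against either trend as the whole cause. Harvest at another time of day stays open: the median absolute difference of 12 clock genes was 0.2026 (bootstrap 95% interval 0.094 to 0.313), against 0.184 for all tested genes and 0.502 for the called genes, which were selected for large differences. Of the 12, CCA1, GI and PRR7 were called and 7 had an unadjusted p under 0.05, against 4980 of all 19596 tested genes. The genotype itself, its growth and unrecorded differences between the seed stocks or plates remain among the open explanations and were not tested.

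The third pattern is the level of POT1B in replicate 3 of pot1b, near that of WT in both treatments. WT RNA in these libraries would draw all genotype-dependent genes toward WT, but the libraries sat at 0.938 and 0.8453 on the scale from WT (0) to pot1b (1), against 0.11 and -0.07 for POT1B itself. Reads of the overlapping NHL3, if a fixed share of them was counted, would follow its level. That level was 1.069 and 0.874 times that of the other pot1b libraries, where POT1B was 2.24 and 3.56 times higher. WT RNA and a rise of NHL3 are argued against as the whole cause. NHL3 stood at 67.9 and 51.5 CPM in these libraries, and reads within the overlap were not examined. A changed share of NHL3 reads counted there is therefore not excluded. Replicate 3 also had the highest POT1B level of its group in WT, at 3.23 CPM under mock and 5.35 CPM under Zeocin. Whether the replicate number mattered for POT1B was not tested. Which part of the transcript the reads came from was not tested either, and a transcript left in the mutant stays open. Both libraries held the pot1b profile at a counted POT1B level near WT. Since the counts may not reflect an intact transcript, they do not tell whether the genotype differences depend on POT1B.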

How the results depend on the processing

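The offsets for GC content and gene length and the fit to genes without overlap were chosen after the results were seen. No called named gene changed direction under RLE scaling, DESeq2, the replicate block or with a library left out, and no called list with an estimated correlation, fry, the block or a library left out. Directions under the other alternatives were not compared. Counts of calls stayed within 1.5 times of those reported under RLE and upper-quartile scaling, without the filter and with the stricter one, with DESeq2, on nuclear protein-coding genes, with thinned libraries, on genes without overlap and with the offsets. With the offsets the share of raised genes fell to 47.5% from 55.8% for Zeocin in WT and to 45.3% from 55.2% in pot1b. The level of POT1B differed by -0.83 under both TMM and RLE scaling.

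The interaction had 91 calls with limma-voom, and the cause was not tested. Fitted to the 6 libraries compared alone, Zeocin in WT gave 709 genes (68.1% of them higher), pot1b against WT gave 3981 under mock and 928 under Zeocin (69.5% higher), and Zeocin in pot1b moved by less than 1.5 times. Such fits estimate the spread from fewer samples, which alone does not account for a rise from 2562 under mock and a fall from 2168 under Zeocin. The main fit shares 1 estimate of the spread among all groups. Replicates differed by a chi-square per degree of freedom of up to 25.8 in WT Zeocin and at most 7.61 in the mock groups. Leaving out WT Zeocin replicate 1 raised the count under mock from 2562 to 3736 and that for Zeocin in pot1b from 1313 to 2033. That library is in neither comparison, so it acted on these counts through steps shared by all libraries. These steps are the spread estimate, the scaling and the filter, and their parts were not tested separately. At an adjusted p under 0.01 the counts were 650, 793, 1400, 986 and 45 (Zeocin in WT, Zeocin in pot1b, genotypes under mock, genotypes under Zeocin, interaction), and with a fold change of at least 2 they were 310, 338, 341, 212 and 33, as stricter thresholds require.

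Leaving out 1 library at a time, the counts ranged from 707 (without WT mock replicate 1) to 1498 for Zeocin in WT and from 919 (without pot1b mock replicate 1) to 2033 for Zeocin in pot1b. They ranged from 1595 (without WT mock replicate 1) to 3736 for the genotypes under mock, from 1239 (without pot1b Zeocin replicate 1) to 2304 for the genotypes under Zeocin and from 56 (without pot1b Zeocin replicate 1) to 437 for the interaction. All upper ends came without WT Zeocin replicate 1, whose differences from the other 2 libraries of its group (chi-square per degree of freedom 25.8 and 23.9) exceeded those within any other group (at most 10.4). Its TMM factor was 1.15. Why it differed was not tested. Of the named genes that were called, 27 of 39, 36 of 45, 50 of 63, 40 of 50 and 12 of 25 were called whichever library was left out, in the order of contrasts above. DESeq2 did not call, or gave no adjusted p for, 4, 1, 6, 6 and 11 of them.

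The replicate number as a block gave 379 interaction calls and moved no other count past 1.5 times. Among named genes and lists it ended no call and added 9 gene and 5 list calls. The labels do not say what the numbers mark, and the numbers were not taken to pair the samples, since only 12 of 18 same-numbered pairs of libraries had a correlation of their deviations above 0.1. Number 3 ran from 0.29 to 0.416, number 1 from 0.08 to 0.295 and number 2 from -0.022 to 0.141, and 9 of 12 libraries correlated best with their own number, a hint from the data and not the design. On the third principal component (13.3% of the variance) replicate 3 was the lowest library of each group. A factor shared by the replicate 3 libraries is therefore not excluded. For lists, an estimated correlation ended 12 calls of camera. Fry, whose question differs since it compares a list with no other genes, called 18 list results that camera did not and left 1 of camera's uncalled. Among the 18, the G2/M list was higher with Zeocin in WT and pot1b (fry adjusted p = 0.011 and 0.0016). The G2/M list was lower in pot1b than in WT under mock and Zeocin (fry adjusted p = 0.0013 and 0.030). The S-phase list was higher with Zeocin in WT and pot1b (fry adjusted p = 0.032 and 0.037).

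Depth limits what can be said of low genes. POT1B had 8 to 56 counts per pot1b library, and small differences in it were not detectable.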

Other observations

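The product families below and the shares of organelle reads were examined only after the main results were seen. Tau-class glutathione transferases, which detoxify reactive molecules, were higher in pot1b in 9 of 23 genes and lower in 2 under mock (camera adjusted p = 0.016) and higher in 12 and lower in 1 under Zeocin (5.2e-09), with GSTU26 at 1.56, GSTU6 at 1.77 and GSTU5 at 1.14 under Zeocin. With an estimated correlation these adjusted p-values were 0.50 and 0.16. Cysteine-rich receptor-like kinases were higher in 8 of 24 and lower in 0 under mock (4.0e-06), and WRKY transcription factor genes in 10 of 40, with 1 lower (0.00065), but the values were 0.50 and 0.75 with an estimated correlation. Of Aux/IAA auxin repressor genes 5 of 14 were lower in pot1b under mock (0.016), and SAUR genes, which respond to auxin, were lower in 9 of 42 and higher in 3 (0.013), but both values were 0.50 with an estimated correlation. Under Zeocin JAZ genes were higher in 4 of 10 (0.015) and xyloglucan transferase genes lower in 4 of 20 and higher in 1 (0.025), against 0.65 and 0.42 with an estimated correlation.

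Zeocin raised 11 of 40 WRKY genes (0.00078) and 11 of 55 TIR-type immune receptor genes (0.0015) in WT, and lowered 3 of 11 GH3 genes in pot1b (0.044). With an estimated correlation these values were 0.99, 0.17 and 0.68. The Aux/IAA genes had a higher Zeocin effect in pot1b in 3 of 14 (0.0014, but 0.41 with an estimated correlation). Of 220 families 6, 3, 16, 14 and 8 were called in the contrasts (Zeocin in WT, Zeocin in pot1b, genotypes under mock, genotypes under Zeocin, interaction), and with an estimated correlation 0 in each.

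Mitochondrial genes took 0.745 ± 0.007% of counts in WT mock, 0.632 ± 0.029% in WT Zeocin, 0.582 ± 0.031% in pot1b mock and 0.669 ± 0.025% in pot1b Zeocin (SD, n = 3). The share was lower with Zeocin in WT, higher with Zeocin in pot1b and lower in pot1b than in WT under mock, each at an exact permutation p of 0.1, the smallest that 3 against 3 can give, and p was 0.2 between the genotypes under Zeocin. The chloroplast gene psbA took 31.0 ± 1.29%, 30.8 ± 3.69%, 34.6 ± 2.04% and 32.3 ± 1.5% in the same order of groups, with an exact permutation p = 1 for Zeocin in WT, 0.2 for Zeocin in pot1b, 0.1 between genotypes under mock and 0.7 under Zeocin. The groups of 3 did not overlap in 34.6% of genes between genotypes under mock, 26% under Zeocin, 22% for Zeocin in WT and 25.2% for Zeocin in pot1b, where chance gives 10%.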
